A study of Homo sapiens with 16 samples.

How the data were processed

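The 16 samples were arrays of VCaP cells, a prostate cancer line that makes ERG from a fusion of TMPRSS2 to ERG. Per the labels, the cells carried a doxycycline-inducible hairpin, either a nontargeting control or a hairpin against ERG, and grew in 100 ng/ml doxycycline for 1, 3, 7 or 10 days. Each of the 8 combinations of hairpin and day had 2 arrays, called replicate 1 and replicate 2 here from the marks in the sample titles. RNA was extracted with RNeasy columns, amplified with the NuGEN Ovation kit, labelled with biotin and hybridized to Affymetrix HG-U133 Plus 2.0 arrays. The growth protocol in the labels mentions cells without doxycycline, but none of the 16 arrays came from such cells. Each arm held a single hairpin, so an effect of lowering ERG could not be separated from another effect of that hairpin. Nothing in the labels says that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

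The deposited values were intensities on a linear scale for 54675 probe sets per array, made with MAS5 per the submitters' processing notes. The software release was not given in the sources used here. The mean of each array after trimming 2% at each end lay between 150.02 and 150.023, so the arrays had been scaled to one target. The median signal per array ran from 19.3 to 26.1. Spearman correlations between arrays, computed across probe sets, lay between 0.876 and 0.919, and probe sets are not independent replicates. The number of arrays limits the precision.

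Signals were turned into log2 values after adding 15. Of the probe sets, 41091 named 1 gene, 1801 named several, 11721 named none and 62 were array controls. The symbols of 41043 of those with 1 gene were matched to current gene symbols. Probe sets with a mean log2 value above the median of all probe sets, 5.15, a signal of 20.5, were kept, and each gene was taken from its kept probe set with the highest mean, which left 12201 genes. More than 1 kept probe set was present for 6149 of them. Among the 78 named genes, 45 had several kept probe sets and 4 of these had at least 1 probe set with the opposite sign.

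Group means were fitted per gene with limma 3.58.1 in R 4.3.3, with empirical Bayes variances that followed a trend in mean signal. The fit had 8 residual degrees of freedom, and 13 in total after moderation. The difference of ERG shRNA minus control shRNA was tested as the average over the 4 days and on each day. Differences between the days in that effect were tested over all days and as day 10 minus day 1, and the control arm was compared between day 10 and day 1. P-values were two-sided and were adjusted by Benjamini and Hochberg over all genes of a comparison, with a threshold of 0.05. Errors given with a log2 difference are standard errors from the fit, and errors given with a signal are standard deviations.

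There were 18 gene lists, each compared with all other genes by camera with a preset correlation of 0.01, and their p-values were adjusted together. They held genes often higher in ERG-positive prostate cancer, other ETS factors, androgen-induced genes, luminal, basal, and neuroendocrine markers, S-phase genes, mitotic genes, mesenchymal genes, nucleolar genes, p53 targets, interferon response genes, genes of the ATF4 stress response, respiratory chain genes, cholesterol synthesis genes, hypoxia genes, Wnt targets, and markers of stromal, endothelial and immune cells. Only members with a kept probe set were measured. These were 5 of 17 for the basal list, 6 of 20 for the stromal, 8 of 20 for the mesenchymal and 8 of 14 for the Wnt list. The result of a list covers its measured members alone. Each test was repeated with a correlation estimated from the residuals. That form of the test also uses only the residual degrees of freedom, so a lost call cannot be credited to correlation alone. The neuroendocrine list had an estimated correlation of -0.0269, under the preset one, yet its adjusted p on average went from 5.53e-11 to 0.00123. With the estimated correlation, the average calls that held were those of the ERG-positive and neuroendocrine lists.

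The comparisons, lists, settings, alternatives and the rule for naming genes were chosen before the data were examined. The rule named 6 fixed genes, the 10 largest average rises and the 10 largest falls among genes past the threshold with 1 sign on all 4 days, the 3 largest rises and falls of each day, the 5 largest of each comparison of day 10 with day 1, and the 3 members of each list with the smallest adjusted p. Probe sets without a single gene, uncharacterized loci and genes of the sex chromosomes that differ by sex were passed over. Of the 6 fixed genes, 1 had no probe set with its symbol and is not analysed here. Genes outside the rule are said to have been chosen after their values were seen.

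The alternatives were quantile normalization, an added constant of 0 or 60, no filter, a filter at the 0.75 quantile, the mean of a gene's probe sets, every probe set as its own test, a term for the replicate, variances without a trend, a fit of only the arrays compared, an additive fit of hairpin and day, the estimated correlation, and leaving out each array. Chosen after the data were seen were a fit with the same-day arrays of equal replicate number as 8 blocks, which has 4 residual degrees of freedom, fits without the day 7 or the day 1 arrays, and tests of 4 gene families. Same-day arrays with equal replicate numbers were more alike than unequal ones: after removal of group means, the correlations across genes of their residuals were 0.308, 0.434, 0.647 and 0.378 on days 1, 3, 7 and 10, and genes are not independent replicates. Equal numbers on different days gave 0.0159 to 0.404.

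The fit was tested on simulated data of the same size, without pairing between arrays, with 100 genes planted at each of several differences. The average test called 49% of genes planted at a log2 difference of 0.5 and 86% at 1, with 7 false calls, and with blocks 29% and 79%, with 2 false calls. The day 10 test called 1% and 31%, with 4 false calls, and with blocks 0% of both. The day 1 test called 5% and 33%, with 4 false calls. A list shifted by -0.50 had an adjusted p of 2.65e-32 and no other list was called. The simulated genes were drawn independently of each other. This therefore does not measure false calls of lists whose genes move together. In the real arrays the estimated correlation was 0.784 for the S-phase list and 0.946 for the mitotic list.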

Results

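Transcripts were measured in VCaP prostate cancer cells after 1, 3, 7 and 10 days of doxycycline, which switched on either a control hairpin or a hairpin against ERG, the ETS transcription factor that these cells make from a gene fusion. There were 2 arrays for each hairpin on each day, 8 arrays per arm and 16 in all. Each array gave a signal for 54675 probe sets, and 12201 genes were tested. The question was which transcripts differed when ERG was lowered, and how this developed over the 10 days. Log2 differences are ERG shRNA minus control shRNA unless stated otherwise, and a pair is the control and the ERG shRNA array of 1 day with the same replicate number.

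The target itself was lower in the ERG shRNA arm on every day. By its brightest probe set, ERG fell from a mean signal of 2366 ± 282 (SD, n = 8) to 1489 ± 316 (SD, n = 8), a log2 difference of -0.68 (SE 0.11, adjusted p = 0.00215). It was lower in 8 of 8 pairs. With this probe set the control groups had means of 2276 ± 123, 2562 ± 1.06, 2324 ± 640 and 2302 ± 168 (SD, n = 2) on days 1, 3, 7 and 10, while the ERG shRNA groups had 1385 ± 61.3, 1785 ± 270, 1534 ± 555 and 1250 ± 33.7 (SD, n = 2). The log2 differences on those days were -0.71, -0.53, -0.61 and -0.87. With 2 arrays a group, none passed the test on a single day, with adjusted p of 0.682, 0.676, 0.329 and 0.11. The other 3 ERG probe sets had larger average differences, of -0.94, -0.94 and -1.15. With every probe set as its own test and no filter, 1 of these passed on a single day, day 7 (-1.31, SE 0.22, adjusted p = 0.0397, 2 of 2 pairs). The signal left in the ERG shRNA arm was 62.9% of control with the brightest probe set and 51.6%, 51.2% and 42% with the others.

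**Figure D1:**
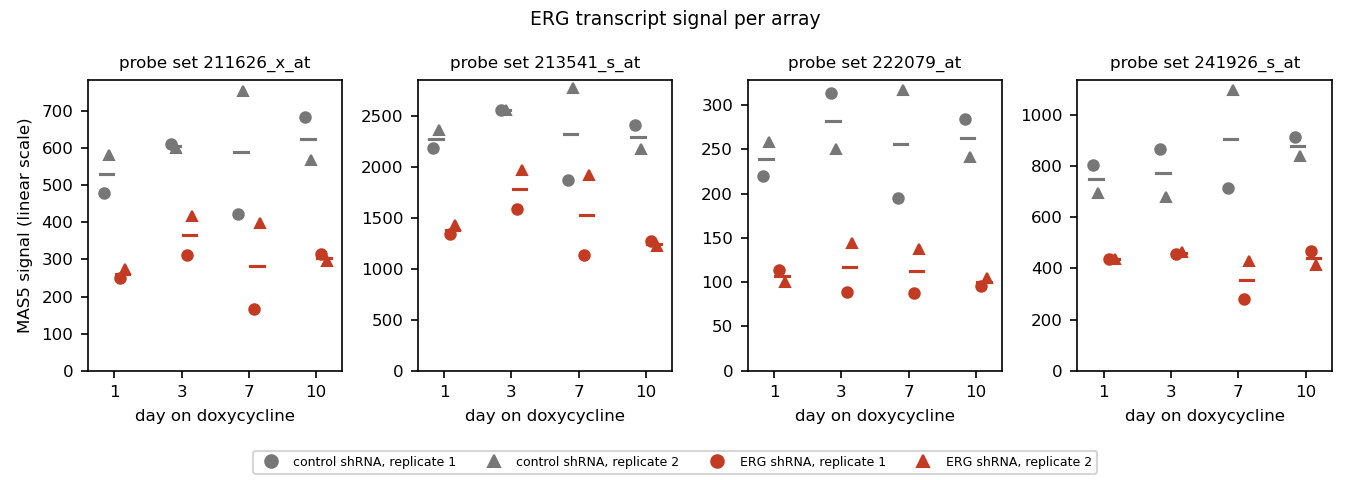
Signal of the 4 ERG probe sets (linear MAS5 scale) on each array by day of doxycycline, with control shRNA in grey, ERG shRNA in red, circles for replicate 1, triangles for replicate 2 and bars for the mean of 2 arrays. In the brightest probe set the control means lay between 2276 and 2562 and the ERG shRNA means between 1250 and 1785.

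TMPRSS2, an androgen-induced serine protease whose promoter drives the fusion, rose from 3508 ± 792 to 5963 ± 1500 (SD, n = 8), a log2 difference of 0.75 (SE 0.13, adjusted p = 0.00261, higher in 7 of 8 pairs). KLK3, which encodes prostate-specific antigen, had means of 481 ± 94.1 and 982.3 ± 496 (SD, n = 8), a difference of 0.84 (SE 0.26, higher in 7 of 8 pairs) that did not pass the test (adjusted p = 0.0642) and was 0.54 with the mean of its probe sets. KLK3 passed with the pairs as blocks (adjusted p = 0.0216), without the ERG shRNA day 1 replicate 2 array (0.00645) and without the ERG shRNA day 3 replicate 2 array (0.0215). It also passed with a term for the replicate (0.033), in the additive fit (0.0432) and without the day 1 arrays (0.014). Of its 3 probe sets, 1 had a difference of -0.02. MYC, a growth-promoting transcription factor, had signals of 5416 and 5374 and a difference of -0.01 (adjusted p = 0.987, higher in 4 of 8 pairs). PAK4, a kinase that gives the control hairpin its name in the labels, rose by 0.44 (SE 0.11, adjusted p = 0.0263), from 339.7 ± 109 to 452.9 ± 96.7 (SD, n = 8), and was higher in 7 of 8 pairs. The PAK4 call was lost when any of 8 arrays was left out, namely control day 1 replicate 1 (0.068), day 3 replicates 1 (0.0662) and 2 (0.0514) and day 10 replicates 1 (0.0539) and 2 (0.065), and ERG shRNA replicate 2 of days 1 (0.0549), 3 (0.0586) and 10 (0.0707). It was also lost without the day 7 arrays (0.102). PAK4 passed with the pairs as blocks (adjusted p = 0.000889), and its other kept probe set had a difference of 0.64.

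Over the 4 days, the largest rises among the named genes included transcripts with a low signal in the control arm. RLN1, a relaxin peptide hormone, rose from a signal of 70.88 to 1916, a log2 difference of 3.87 (SE 0.41, adjusted p = 8.32e-05, higher in 7 of 8 pairs). CRISPLD1, a secreted protein, rose from 24.32 to 591, by 3.41 (SE 0.42, adjusted p = 0.000286), with 2.49 and 4.23 when 60 or 0 was added to the signal. LRRTM4, a synaptic adhesion protein, rose from 7.712 to 182.6, by 2.65 (SE 0.15, adjusted p = 1.02e-06). The LRRTM4 control signal lay under the filter signal of 20.5, so the size of its difference was set by the constant added, with 1.54 when 60 and 4.31 when 0 was added, and the call was kept with both. DDC, the decarboxylase that makes dopamine and serotonin, rose from 273.4 to 1448, by 2.39 (SE 0.19, adjusted p = 1.14e-05). RORB, an orphan nuclear receptor, rose by 2.62 to a signal of 438.2, and GPR158, an orphan receptor of the nervous system, by 2.47 to 509.4. LRATD1 rose by 2.42, the lipid transporter ATP8B4 by 2.23 and lumican, a matrix proteoglycan encoded by LUM, by 2.32. Other kept probe sets of LRATD1, LUM and DDC had differences as small as 0.51, 0.88 and 1.15. ADAMTS1, a secreted metalloprotease, rose from 360.3 to 2328, by 2.34 (SE 0.38, adjusted p = 0.00165, higher in 7 of 8 pairs). The other 8 of these 10 genes were higher in 8 of 8 pairs, and their adjusted p ran from 1.02e-06 to 0.000944.

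Among the largest falls, ADGRG6, an adhesion receptor coupled to G proteins, fell from a signal of 1219 to 196.1, a log2 difference of -3.03 (SE 0.29, adjusted p = 4.08e-05). MGP, an inhibitor of calcification in matrix, fell from 1555 to 285.3, a difference of -2.58 (SE 0.28, adjusted p = 0.000103). GDA, which deaminates guanine, fell from 361.1 to 54.61, with -2.49 (SE 0.12, adjusted p = 3.88e-07). ARHGDIB fell from 1670 to 351.2, with -2.45 (SE 0.21, adjusted p = 2.15e-05), though another of its 3 kept probe sets had -0.37. CXCL11, a chemokine, fell from 2393 to 553, with -2.18 (SE 0.21, adjusted p = 4.35e-05, lower in 7 of 8 pairs), and ACKR3, a scavenging receptor for CXCL11, fell from 431.8 to 128.3, with -1.80, or -1.08 with the mean of its 2 probe sets, of which the other had -0.36. SLPI, a secreted protease inhibitor, had -2.20, TCF7L2, a transcription factor of the Wnt pathway, -2.11, tenascin C, encoded by TNC, -2.07 and CDCA7L -2.00. Apart from CXCL11, each of these 10 genes was lower in 8 of 8 pairs.

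**Figure D2:**
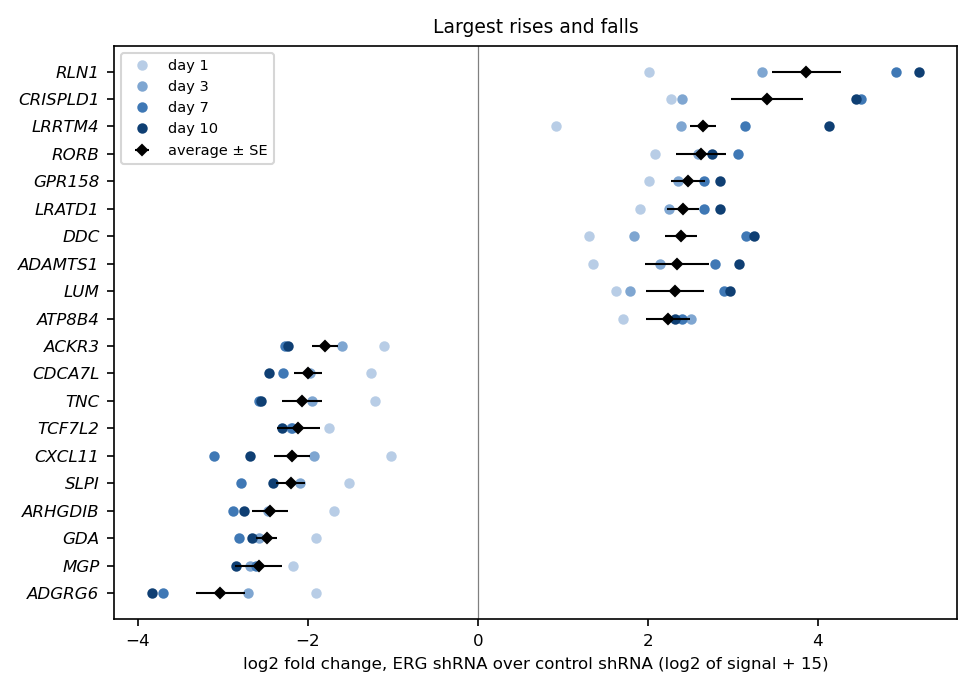
Log2 difference, ERG shRNA minus control shRNA, on each of the 4 days (blue points, darker with the day) and as the average with its SE (black diamonds and bars) for the 10 largest rises and the 10 largest falls. RLN1 had the largest average rise, 3.87, and ADGRG6 the largest average fall, -3.03.

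In total 978 of 12201 genes changed on average, 566 higher and 412 lower, and 962 of them had the same sign on all 4 days. At least 2-fold differences made up 197 of these, 135 higher and 62 lower. With the pairs as blocks, a fit called the blocked fit from here on, 2588 genes passed, 1313 higher and 1275 lower, among them all 978. Some genes differed between the pairs of day 1, and the genes compared here were chosen after their values were seen. In the replicate 2 pair RLN1 differed by -0.05, ADAMTS1 by -0.35, CXCL11 by 0.16 and TMPRSS2 by -0.30, against 4.06, 3.06, -2.19 and 1.01 in the replicate 1 pair of day 1, while the mean of the ERG probe sets differed by -0.92 and -0.83. Other genes were alike in both pairs, with GDA at -1.75, TUNAR at 1.61, CHGB at 0.99 and HLA-DMB at -1.30 in replicate 2 against -2.06, 1.93, 0.94 and -1.30 in replicate 1.

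Among the 22 measured genes often higher in ERG-positive prostate cancer, 10 fell, none rose and 12 did not pass, and 13 were lower when adjusted over the list alone. The list's median log2 difference was -0.39 and its adjusted p 7.46e-10, which stayed past the threshold with an estimated correlation (adjusted p = 0.0139), though not when that was joined to blocks for the pairs (adjusted p = 0.127). Its mean was lower in 8 of 8 pairs, from -0.30 in the replicate 2 pair of day 1 to -0.82 in the replicate 1 pair of day 7. HLA-DMB, which loads peptides on class II molecules, fell from a signal of 1634 to 548.7 (-1.62, SE 0.13, adjusted p = 1.14e-05), and YAP1, the effector of the Hippo pathway, from 752.1 to 321.2 (-1.18, SE 0.12, adjusted p = 8.09e-05). ARHGDIB was the third member named by the rule. List members beyond the 3 with the smallest adjusted p were chosen after their values were seen, here and in the lists that follow. They included the lipase PLA1A at -0.91, the Wnt receptor FZD4 at -1.04, the potassium channel subunit KCNS3 at -1.01, the calcium channel CACNA1D at -0.66, CRISP3 at -0.58 and the histone deacetylase HDAC1 at -0.31, all of which fell.

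Neuroendocrine and neuronal markers rose, with 8 of 17 measured genes higher, none lower and 9 that did not pass, and 9 higher when adjusted over the list alone. The list's median was 0.45, its adjusted p was 5.53e-11 and 0.00123 with an estimated correlation, and its mean was higher in 8 of 8 pairs, from 0.55 to 0.90. Beside DDC, the granule proteins chromogranin B (CHGB, 0.96, SE 0.08, adjusted p = 1.41e-05) and chromogranin A (CHGA, 1.48, SE 0.15, adjusted p = 5.18e-05) rose in 8 of 8 pairs, CHGA from a signal of 136.8 to 421.7. The secretogranins SCG2 and SCG3 rose by 2.09 and 1.20, the vesicle protein SYT4 by 1.36, the microtubule protein MAP2 by 0.69 and the ubiquitin hydrolase UCHL1 by 0.45. Synaptophysin, encoded by SYP, had a difference of 0.39 and the neuroendocrine transcription factor INSM1 of -0.07, and neither passed.

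**Figure D3:**
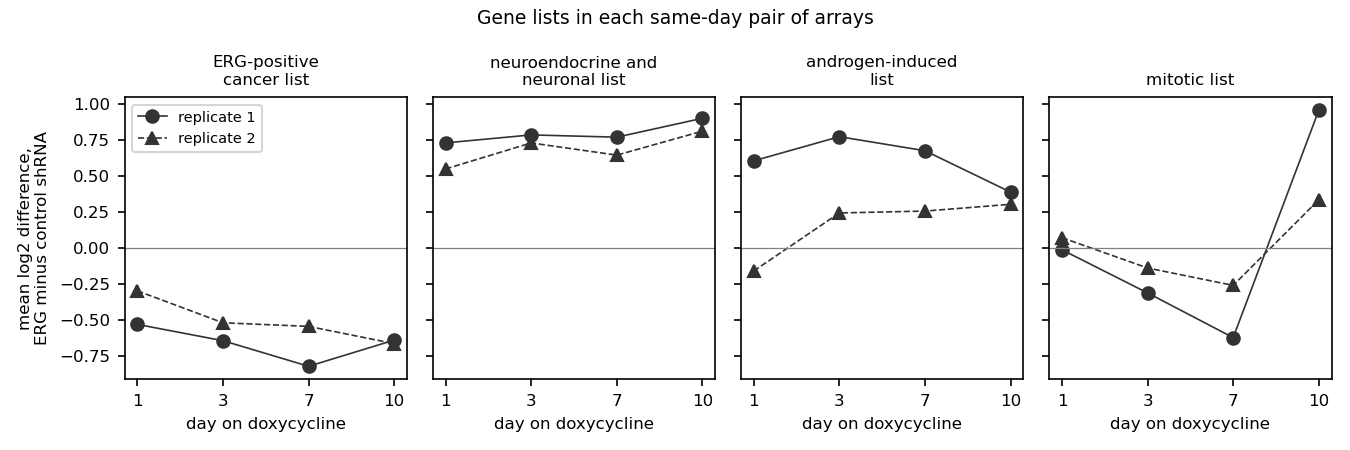
Mean log2 difference, ERG shRNA minus control shRNA, of the measured members of 4 gene lists in each of the 8 same-day pairs by day of doxycycline, with circles for replicate 1, triangles for replicate 2 and lines that only join equal replicate numbers. The list of genes often higher in ERG-positive prostate cancer lay below 0 in all 8 pairs and the neuroendocrine list above 0 in all 8.

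Of 26 androgen-induced genes, 9 rose, 2 fell and 15 did not pass, and 12 were higher and 2 lower when adjusted over the list alone. The median was 0.20 and the adjusted p 0.000289, or adjusted p = 0.467 with an estimated correlation, and the mean was higher in 7 of 8 pairs, with -0.16 in the replicate 2 pair of day 1. The transcription factor MAF (1.26, SE 0.13, adjusted p = 7.19e-05), the steroid receptor chaperone FKBP5 (0.68, SE 0.10, adjusted p = 0.00113) and the prostate transporter SLC45A3 (1.48, SE 0.24, adjusted p = 0.00156) rose, SLC45A3 in 7 of 8 pairs and the others in 8. Against the list's name, NDRG1, a stress-induced gene, fell by 0.49 and UAP1, an enzyme of hexosamine synthesis, by 0.43. The kallikrein KLK2 had a difference of 0.06 and did not pass (adjusted p = 0.752). Among 14 ETS factors other than ERG, ELK3 (-0.98, SE 0.16, adjusted p = 0.00156) and ELK4 (-0.32, SE 0.09, adjusted p = 0.0372) fell and were lower in 8 of 8 pairs. The luminal factor SPDEF rose (0.42, SE 0.11, adjusted p = 0.0367, 8 of 8 pairs). The other 11 did not pass, and 1 was higher and 2 lower adjusted over the list alone. The ETS list had a median of -0.14 and did not pass (adjusted p = 0.253). In the blocked fit 4 of its members were lower and 1 higher. The calls of SPDEF and ELK4 were each lost when any of 11 of the 16 arrays was left out. The adjusted p reached 0.1 for SPDEF without ERG shRNA day 1 replicate 1 and 0.105 for ELK4 without control day 3 replicate 1. SPDEF and ELK4 were also lost with the mean of their probe sets (0.23, adjusted p = 0.126, and -0.06, adjusted p = 0.769), without the variance trend (0.0529 and 0.0505), without the day 7 arrays (0.0602 and 0.0879) and without the day 1 arrays (0.113 and 0.11). A further ELK4 probe set had a difference of 0.57.

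Luminal markers moved both ways: of 19 measured, 3 rose, 2 fell and 14 did not pass, with 5 higher and 2 lower adjusted over the list alone. CD24 rose by 0.57 (SE 0.09, adjusted p = 0.00112, 8 of 8 pairs) and the peptidase DPP4 by 1.03 (SE 0.21, adjusted p = 0.00716, 8 of 8 pairs). AGR2, a disulfide isomerase of secretory cells, fell by 0.76 (SE 0.11, adjusted p = 0.000697, 8 of 8 pairs). The luminal factor FOXA1 had a difference of 0.00. The luminal list had a median of 0.00 and did not pass (adjusted p = 0.547). Luminal members past the threshold were 5 higher and 4 lower in the blocked fit. Of 5 basal markers, the adhesion receptor CD44 rose from a signal of 51.42 to 300.6 (2.15, SE 0.17, adjusted p = 1.14e-05, 8 of 8 pairs), the integrin ITGA6 fell (-0.61, SE 0.14, adjusted p = 0.0146, 7 of 8 pairs) and 3 did not pass. Adjusted over the list alone 1 was higher and 1 lower. CD44 was higher by all 8 of its kept probe sets, with differences as small as 0.59. The basal list had a median of 0.30 and an adjusted p of 0.332, and in the blocked fit 2 basal markers were higher and 1 lower. Among 8 mesenchymal and invasion genes, TNC, the collagen COL5A2 (-1.38, SE 0.20, adjusted p = 0.000717, 8 of 8 pairs) and the lysyl oxidase LOX (-1.05, SE 0.19, adjusted p = 0.00393, 7 of 8 pairs) fell, with -0.84 and -0.66 for COL5A2 and LOX when 60 was added to the signal. Fibronectin (FN1, 1.03, SE 0.28, adjusted p = 0.04) rose and 4 did not pass, and adjusted over the list alone 3 were lower and 1 higher. The mesenchymal list had a median of -0.14 and an adjusted p of 0.0422, which was 0.0778 with the pairs as blocks, and adjusted p = 0.426 with an estimated correlation. Its call was also lost without control day 1 replicate 1 (0.0859), day 3 replicate 2 (0.0542), day 7 replicate 2 (0.0567) or day 10 replicate 2 (0.0813), and without ERG shRNA day 1 replicate 2 (0.135), day 3 replicate 1 (0.0707), day 7 replicate 1 (0.0666) or day 10 replicate 2 (0.0621). Of 6 stromal, endothelial and immune markers, LUM rose, the smooth muscle actin ACTA2 fell (-1.19, SE 0.19, adjusted p = 0.00184, 8 of 8 pairs) and 4 did not pass, with the same counts adjusted over the list alone. That list's median was -0.09 and its mean 0.17, the test pointed down, and it did not pass (adjusted p = 0.954).

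Few genes of cell division passed the test on average. Of 29 S-phase and DNA replication genes, the polymerase POLA1 fell (-0.64, SE 0.11, adjusted p = 0.00197, 8 of 8 pairs) and 28 did not pass. Adjusted over the list alone 1 was lower. The S-phase list had a median of -0.19 and an adjusted p of 0.0414, or adjusted p = 0.873 with an estimated correlation, and its mean was lower in 7 of 8 pairs, with 0.11 in the replicate 2 pair of day 1. Of its members 6 were lower and 1 higher in the blocked fit. The lower ones included the helicase subunits MCM3 (-0.37, 0.13 without and 0.00924 with blocks, lower in 7 of 8 pairs) and MCM7 (-0.40, 0.142 without and 0.000775 with blocks, lower in 8 of 8 pairs). MCM3 also passed without ERG shRNA day 7 replicate 1 (0.032) or day 1 replicate 2 (0.0466), and MCM7 without the latter (0.0215) or without the day 1 arrays (0.0285). The S-phase call was lost without control day 1 replicate 2 (0.0995), day 3 replicate 1 (0.0855), day 7 replicate 1 (0.326) or day 10 replicate 1 (0.228), and without ERG shRNA day 1 replicate 1 (0.151), day 3 replicate 2 (0.142), day 7 replicate 2 (0.639) or day 10 replicate 2 (0.394). None of 30 mitotic genes passed, including adjusted over the list alone. The proliferation marker MKI67 had a difference of -0.23 (adjusted p = 0.765), which passed with the pairs as blocks (adjusted p = 0.0379) and was lower in 6 of 8 pairs. Its difference ran from -0.47 to 0.0037 over the alternatives, and a further kept probe set had 0.0033. The mitotic list had a median of 0.03, a mean of 0.00 and an adjusted p of 0.954, which was 0.0303 without control day 7 replicate 1. Of the mitotic members 2 were lower in the blocked fit. This average spans days of opposite sign: on day 7 the mitotic list had a median of -0.47 with 1 of 30 members positive (adjusted p = 0.0261, or adjusted p = 0.769 with an estimated correlation). On day 10 it had a median of 0.58 with 30 of 30 positive (adjusted p = 0.000854, or adjusted p = 0.715 with an estimated correlation). The list means were -0.62 and -0.26 in the replicate 1 and 2 pairs of day 7 and 0.95 and 0.33 in those of day 10. No single mitotic gene passed on these days, and in the blocked fit 8 were lower on day 7 and 15 higher on day 10. Of 17 nucleolar genes and 25 respiratory chain genes none passed, including adjusted over the list alone, with medians of -0.05 and 0.01 and adjusted p of 0.547 and 0.954. Nucleolin (NCL) had a difference of -0.12 (adjusted p = 0.314, lower in 7 of 8 pairs) and the complex I subunit NDUFV2 of 0.14 (adjusted p = 0.284). Respiratory chain genes past the threshold were 1 higher and 2 lower in the blocked fit.

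Of 17 p53 targets, the death receptor FAS fell from a signal of 3694 to 1327 (-1.52, SE 0.13, adjusted p = 2.38e-05, 8 of 8 pairs). The stress protein TP53INP1 also fell (-0.54, SE 0.13, adjusted p = 0.0219, 8 of 8 pairs). The RNA-binding protein ZMAT3 rose (0.86, SE 0.16, adjusted p = 0.00376, 8 of 8 pairs, 0.51 with 60 added to the signal). The other 14 did not pass, and 2 were higher and 2 lower adjusted over the list alone. The p53 list had a median of 0.08, a mean of -0.01, a test that pointed up and an adjusted p of 0.852. In the blocked fit 2 members were higher and 2 lower. The cell cycle inhibitor CDKN1A had a difference of 0.48 (adjusted p = 0.0723 without and 0.00451 with blocks) and the p53 antagonist MDM2 of 0.04. The TP53INP1 call was lost without ERG shRNA day 1 replicate 1 (0.0639) or day 10 replicate 1 (0.052), and without control day 1 replicate 2 (0.0562), day 3 replicate 2 (0.0532) or day 10 replicate 2 (0.0626). It was also lost without the day 1 arrays (0.0539). Of 13 interferon response genes, the RNA sensor IFIH1 fell (-0.44, SE 0.10, adjusted p = 0.0168, 7 of 8 pairs, 0.0518 without control day 10 replicate 1) and 12 did not pass, with 1 lower adjusted over the list alone. The IFIH1 call was also lost with the mean of its probe sets (0.195) and without the day 7 arrays (0.0997). The interferon list had a median of -0.27 and an adjusted p of 0.0414, or adjusted p = 0.467 with an estimated correlation, and its mean was lower in 7 of 8 pairs, with 0.06 in the replicate 1 pair of day 7. In the blocked fit it did not pass (adjusted p = 0.0612), while 5 members were lower. Its call was lost without ERG shRNA day 1 replicate 1 (0.0659), day 3 replicate 2 (0.0695), day 7 replicate 2 (0.12) or day 10 replicate 2 (0.085), and without control day 1 replicate 2 (0.0995) or day 7 replicate 2 (0.0567). Of 19 genes of the ATF4 stress response, the lipoprotein receptor VLDLR fell (-0.75, SE 0.14, adjusted p = 0.00398, 8 of 8 pairs) and 18 did not pass, with 1 lower adjusted over the list alone. The stress list had a median of -0.07 and an adjusted p of 0.522, which was 0.0489 without control day 3 replicate 1, 0.0303 without control day 7 replicate 1 and 0.0337 without ERG shRNA day 7 replicate 2. Stress genes past the threshold were 5, all lower, in the blocked fit.

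Of 13 measured cholesterol synthesis genes, SC5D, a sterol desaturase, rose (0.63, SE 0.17, adjusted p = 0.0362, 7 of 8 pairs). The other 12 did not pass, and 3 were higher adjusted over the list alone. The list had a median of 0.33 and an adjusted p of 0.00385, or adjusted p = 0.498 with an estimated correlation, and 0.0567 without control day 7 replicate 2. Its mean was higher in 6 of 8 pairs, with -0.13 and -0.07 in the replicate 2 pairs of days 1 and 3 against 0.30 and 0.45 in those of replicate 1. In the blocked fit 7 members were higher, among them HMGCS1, the synthase before the rate-limiting step (0.80, 0.061 without and 0.00174 with blocks, 6 of 8 pairs), and the epoxidase SQLE (0.64, 0.0845 without and 0.00157 with blocks, 7 of 8 pairs). The SC5D call was lost when any of 12 of the 16 arrays was left out, with adjusted p up to 0.0909 without ERG shRNA day 1 replicate 1. It was also lost without a filter (0.0516), with the mean of its probe sets (0.103), without the variance trend (0.0535) and without the day 7 arrays (0.118). HMGCS1 passed without control day 7 replicate 1 (0.0224) or ERG shRNA replicate 2 of day 1 (0.0249) or day 3 (0.0132). SQLE passed without control day 7 replicate 1 (0.0194) or ERG shRNA replicate 2 of day 3 (0.029) or day 7 (0.048). With a term for the replicate HMGCS1 (0.0058) and SQLE (0.0146) passed, as did HMGCS1 in the additive fit (0.049). Of 18 hypoxia and glycolysis genes, NDRG1 (-0.49, SE 0.09, adjusted p = 0.00344, 8 of 8 pairs), enolase (ENO1, -0.36, SE 0.08, adjusted p = 0.015, 8 of 8 pairs) and ANKRD37 (-0.49, SE 0.13, adjusted p = 0.0325) fell. Hexokinase 2 (HK2, 0.58, SE 0.12, adjusted p = 0.0106, 7 of 8 pairs), a glycolytic enzyme, rose and 14 did not pass. The ENO1 call was lost with the mean of its probe sets (0.0865) and the HK2 call without the day 7 arrays (0.0502), and with the mean of its probe sets HK2 had 0.37. Adjusted over the list alone 2 were higher and 5 lower. The hypoxia list had a median of -0.25 and an adjusted p of 0.0327, or adjusted p = 0.471 with an estimated correlation, and its mean was lower in 7 of 8 pairs, with 0.00 in the replicate 2 pair of day 7. Hypoxia members past the threshold were 7 lower and 2 higher in the blocked fit. Its call was lost without control day 3 replicate 1 (0.0604), control day 7 replicate 1 (0.0615) or ERG shRNA day 3 replicate 2 (0.0916). Of 8 Wnt targets, the transcription factor LEF1 (0.91, SE 0.12, adjusted p = 0.000504, 8 of 8 pairs) and the feedback inhibitor AXIN2 (0.65, SE 0.14, adjusted p = 0.00964, 8 of 8 pairs) rose and 6 did not pass. Adjusted over the list alone 2 were higher. The AXIN2 difference was 0.37 with 60 added to the signal, and its call was lost without the day 7 arrays (0.54, adjusted p = 0.0927). The Wnt list had a median of 0.14 and an adjusted p of 0.121, which was 0.0489 without control day 3 replicate 1.

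On day 1, 2 genes passed, which are the named rise and the named fall of that day. TUNAR, a long noncoding RNA of neural cells, rose by 1.77 (SE 0.18, adjusted p = 0.00342, 2 of 2 pairs), and GDA fell, with -1.91 (SE 0.25, adjusted p = 0.0187, 2 of 2 pairs). The TUNAR call was lost without control day 1 replicate 1 (0.122) or ERG shRNA day 1 replicate 1 (0.104), and the GDA call without these arrays (0.122 and 0.422) or control day 1 replicate 2 (0.312). In a fit of only the day 1 arrays TUNAR (0.118) and GDA (0.19) did not pass, nor did GDA with nothing added to the signal (0.0505). Without control or ERG shRNA day 1 replicate 1 the count was 0, without ERG shRNA day 1 replicate 2 it was 22, and with the pairs as blocks it was 109. At an unadjusted p under 0.05, limma gave 504 genes on day 1, 4.13% of those tested. That was under the share of 0.05 expected without any difference, and with the pairs as blocks the share was 11%.

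On day 3, 31 genes passed, 22 higher and 9 lower. PCGEM1, a prostate long noncoding RNA, rose by 2.76 (SE 0.46, adjusted p = 0.0309), LRRTM4 by 2.39 (SE 0.31, adjusted p = 0.0104) and GPR158 by 2.36 (SE 0.40, adjusted p = 0.0309). GDA fell, with -2.57 (SE 0.25, adjusted p = 0.000636), ARHGDIB with -2.47 (SE 0.42, adjusted p = 0.0341) and SLPI with -2.09 (SE 0.34, adjusted p = 0.0309), and all 6 moved the same way in 2 of 2 pairs. The mean control signals of PCGEM1 (18.35) and LRRTM4 (7.712) over all days lay under the filter signal, and their differences were 1.69 and 1.09 with 60 and 3.78 and 5.48 with 0 added to the signal. The GDA call on day 3 was kept whichever array was left out. The LRRTM4 call was lost without control day 3 replicate 1 (0.151) or 2 (0.122) or ERG shRNA day 3 replicate 1 (0.197). Those of GPR158 and SLPI were lost when any of 9 arrays was left out and those of PCGEM1 and ARHGDIB when any of 10 was, with adjusted p up to 0.318 without ERG shRNA day 3 replicate 1. Without a filter PCGEM1, GPR158 and ARHGDIB (each 0.0561) and SLPI (0.0547) were lost, and without the variance trend GPR158 (0.0535) and ARHGDIB (0.0559). ARHGDIB was lost with the mean of its probe sets (0.154), and LRRTM4 (0.0948), GPR158 and SLPI (both 0.124) in a fit of only the day 3 arrays. The day 3 count was 5 without either control day 1 array, and 58 without either ERG shRNA day 1 array. It was 2 without either control day 3 array or ERG shRNA day 3 replicate 1, 9 without ERG shRNA day 3 replicate 2, 4 when any day 10 array was left out and 326 with the pairs as blocks.

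On day 7, 95 genes passed, 59 higher and 36 lower. RLN1 rose by 4.93 (SE 0.81, adjusted p = 0.0139), CRISPLD1 by 4.51 (SE 0.85, adjusted p = 0.0317) and DDC by 3.16 (SE 0.38, adjusted p = 0.00286). ADGRG6 fell, with -3.70 (SE 0.58, adjusted p = 0.0101), CXCL11 with -3.10 (SE 0.42, adjusted p = 0.00489) and ARHGDIB with -2.88 (SE 0.42, adjusted p = 0.00881), and all 6 moved the same way in 2 of 2 pairs. The DDC call was kept whichever array was left out. Without control day 7 replicate 1 or ERG shRNA day 7 replicate 1, the calls of ADGRG6 (0.0739 and 0.103), CXCL11 (0.0566 and 0.067), ARHGDIB (0.0739 and 0.0702), RLN1 (0.0907 and 0.11) and CRISPLD1 (0.171 and 0.191) were lost. RLN1 was also lost without control (0.0544) or ERG shRNA (0.061) day 7 replicate 2, and CRISPLD1 when any of 10 of the 16 arrays was left out. In a fit of only the day 7 arrays ADGRG6 (0.0721) and CRISPLD1, DDC, CXCL11 and ARHGDIB (each 0.0842) did not pass. The CRISPLD1 difference was 3.14 with 60 and 6.19 with 0 added to the signal. The day 7 count was 58 without either control day 1 array, 146 without either ERG shRNA day 1 array and 47 without either control day 3 array. It was 12 and 58 without control day 7 replicate 1 and 2, 11 and 54 without ERG shRNA day 7 replicate 1 and 2. It was 51 without either control day 10 array, 63 without ERG shRNA day 10 replicate 2 and 799 with the pairs as blocks.

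On day 10, 105 genes passed, 62 higher and 43 lower. RLN1 rose by 5.19 (SE 0.81, adjusted p = 0.0103), CRISPLD1 by 4.44 (SE 0.85, adjusted p = 0.0281) and LRRTM4 by 4.13 (SE 0.31, adjusted p = 6.61e-05). ADGRG6 fell, with -3.83 (SE 0.58, adjusted p = 0.0084), MGP with -2.85 (SE 0.56, adjusted p = 0.0336) and GDF11, a growth factor of the TGF-beta family, with -2.83 (SE 0.45, adjusted p = 0.0104), and all 6 moved the same way in 2 of 2 pairs. The LRRTM4 call was kept whichever array was left out. Without control day 10 replicate 1 or 2 or ERG shRNA day 10 replicate 1 or 2, the calls of RLN1 (0.175, 0.0516, 0.0966 and 0.0942), CRISPLD1 (0.215, 0.171, 0.288 and 0.106) and ADGRG6 (0.149, 0.0516, 0.1 and 0.0665) were lost. That of GDF11 was lost without control day 10 replicate 1 (0.177) or ERG shRNA day 10 replicate 2 (0.0831), and that of MGP when any of 8 arrays was left out, with adjusted p up to 0.316 without control day 10 replicate 1. MGP was also lost without the variance trend (0.0522). The LRRTM4 difference was 2.80 with 60 and 5.46 with 0 added to the signal, and that of CRISPLD1 was 3.64 and 4.89, the latter with an adjusted p of 0.0674. The day 10 count was 3 and 29 without control day 10 replicate 1 and 2, 8 and 24 without ERG shRNA day 10 replicate 1 and 2, 162 and 163 without ERG shRNA day 1 replicate 1 and 2, and 888 with the pairs as blocks.

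The days shared many of the genes they called, all with the same direction. Days 3 and 7 shared 27 genes (0.133 expected in the same direction for independent lists), days 3 and 10 shared 23 (0.144 expected) and days 7 and 10 shared 58 (0.427 expected). The lists were not independent, since all days compared the same hairpins in 1 fit that gave a gene the same spread on each day. Sharing above these values therefore does not by itself show a response to lower ERG. Across all genes, the log2 differences of any pair of days had a Pearson correlation between 0.532 and 0.658, and genes are not independent replicates. Among the 566 genes higher on average, the median difference was 0.49, 0.66, 0.81 and 0.75 on days 1, 3, 7 and 10, and among the 412 lower genes it was -0.43, -0.57, -0.67 and -0.65. These genes were selected on the average of the same values. No gene passed the limma test for a difference between the 4 days (smallest adjusted p = 0.557), with 125 genes at an unadjusted p under 0.05. That was 1.02% of the genes tested, under the share of 0.05 expected without any difference, against 5.57% in the blocked fit. The absence of calls in the main fit is therefore weak evidence that effects were alike on all days. The blocked fit called 0 genes as well, so by this test no single gene was shown to differ in effect between the days.

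For day 10 minus day 1 of the ERG shRNA effect, 241 genes had an unadjusted limma p under 0.05. That was 1.98% of the genes, again under the share expected without any difference, against 7.11% in the blocked fit. The count of genes that passed with limma was 0, and LRRTM4 was nearest to the threshold, at 3.21 (adjusted p = 0.0668). Without ERG shRNA day 1 replicate 1 the count was 1, and with the pairs as blocks 5 genes passed, 4 higher and 1 lower. As lists, mitotic genes had a more positive effect on day 10 than on day 1, with a median of 0.61 and 30 of 30 members positive (adjusted p = 0.00173, or adjusted p = 0.86 with an estimated correlation). The direction of the mitotic list turned without ERG shRNA day 10 replicate 1 (0.447), and its call was lost without control day 1 replicate 1 (0.0548) or control day 10 replicate 2 (0.841). S-phase genes had a median of -0.31 (adjusted p = 0.027, or adjusted p = 0.86 with an estimated correlation). The direction of the S-phase list turned without ERG shRNA day 10 replicate 2 (0.441), and its call was lost without control day 1 replicate 1 (0.413), control day 10 replicate 1 (0.933) or ERG shRNA day 1 replicate 2 (0.759). The genes often higher in ERG-positive prostate cancer had a median of -0.19 (adjusted p = 0.0219, or adjusted p = 0.537 with an estimated correlation). That call was lost without control day 1 replicate 1 (0.0548) or 2 (0.0602), control day 10 replicate 1 (0.294), or ERG shRNA replicate 2 of day 1 (0.35) or day 10 (0.111). Without a filter the S-phase and ERG-positive lists each had 0.133. In the blocked fit the neuroendocrine list (0.115 without and 0.0154 with blocks), the cholesterol list (0.113 and 0.0154) and the ATF4 stress list (0.382 and 7.07e-05) passed as well. With an estimated correlation the blocked fit called none of these, with adjusted p = 0.572, adjusted p = 0.807 and adjusted p = 0.572. The neuroendocrine list also passed with the stricter filter (0.00146). The basal list passed with every probe set as its own test (0.0039), where each probe set counted as a list member and CD44 alone gave 8. The cholesterol list passed with the stricter filter (0.0383), with the replicate as a block (0.0364) and without ERG shRNA day 1 replicate 1 (0.0209), control day 7 replicate 1 (0.0425) or 2 (0.0421) or ERG shRNA day 10 replicate 2 (0.0204).

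Within the control arm, mitotic genes were lower on day 10 than on day 1 as a list, with a median log2 difference of -2.00 and 29 of 30 lower adjusted over the list alone (adjusted p = 2.12e-16, or adjusted p = 0.418 with an estimated correlation). ATF4 stress genes were higher, with a median of 2.08 and 5 of 19 higher adjusted over the list alone (adjusted p = 6.23e-09, or adjusted p = 0.418 with an estimated correlation). Cholesterol synthesis genes had a median of -0.97 with 9 of 13 lower adjusted over the list alone (adjusted p = 9.98e-06) and S-phase genes of -0.79 with none (adjusted p = 6.91e-06). Respiratory chain genes had a median of -0.35 with 4 lower (adjusted p = 8.23e-06), hypoxia genes of -0.51 with 2 lower (adjusted p = 0.00255) and androgen-induced genes of 0.21 with none (adjusted p = 0.0081), a call lost with the mean of probe sets (0.125) and without control day 1 replicate 1 (0.0502). With an estimated correlation the adjusted p of these 5 lists was 0.418, 0.571, 0.418, 0.418 and 0.571. No single gene passed with limma (smallest adjusted p = 0.129), with 2409 genes at an unadjusted p under 0.05. The count was 569, 223 higher and 346 lower, with a term for the replicate, 1 without control day 1 replicate 1, ERG shRNA day 1 replicate 1 or ERG shRNA day 1 replicate 2, and 16 without either control day 7 array.

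**Figure D4:**
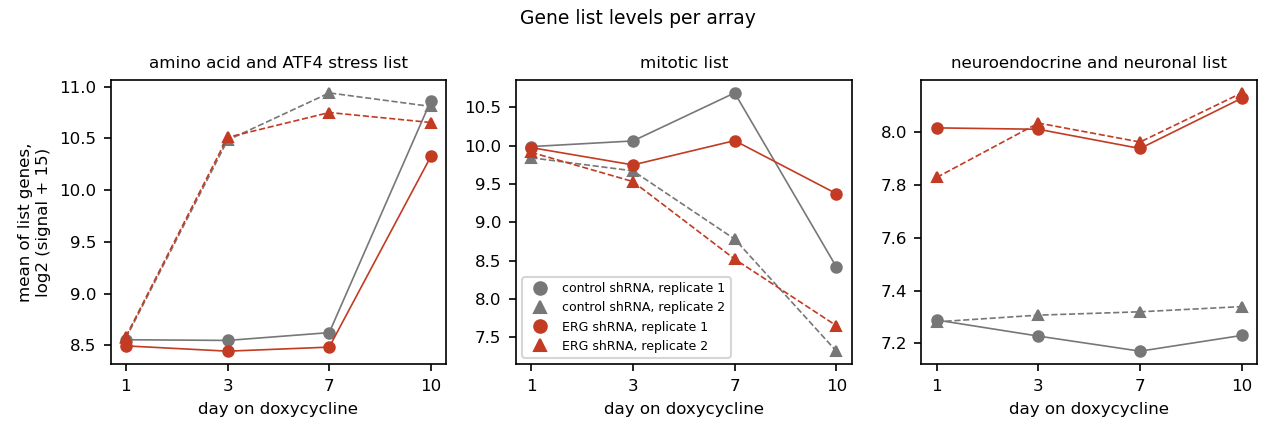
Mean log2 level of the ATF4 stress, mitotic and neuroendocrine lists on each array by day of doxycycline, with control shRNA in grey, ERG shRNA in red, circles for replicate 1, triangles for replicate 2 and lines that only join equal replicate numbers. On days 3 and 7 the control stress level was 8.55 and 8.62 in replicate 1 and 10.48 and 10.94 in replicate 2.

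The replicates of days 3 and 7 differed in the stress list in both arms, and those of days 7 and 10 in the mitotic list. The stress list had levels of 8.55, 8.55, 8.62 and 10.86 in control replicate 1 on days 1, 3, 7 and 10 and of 8.57, 10.48, 10.94 and 10.81 in control replicate 2. The ERG shRNA arm had 8.49, 8.44, 8.48 and 10.33 in replicate 1 and 8.58, 10.51, 10.75 and 10.65 in replicate 2. The mitotic list, replicate 2 minus replicate 1, differed by -0.15, -0.39, -1.91 and -1.10 in the control arm and by -0.06, -0.22, -1.54 and -1.72 in the ERG shRNA arm. Principal components 1 and 2 of all tested genes held 35.4% and 21% of the variance. The ratio of the 3-prime to the 5-prime ACTB control probe sets, a measure of RNA integrity, was 0.428 ± 0.11 in the control arm and 0.432 ± 0.112 in the ERG shRNA arm on the log2 scale (SD, n = 8, exact two-sided permutation p = 0.954 within days). It was at least 0.491 in every replicate 1 array and at most 0.395 in every replicate 2 array. The same ratio for GAPDH was -0.00838 and -0.0389 (exact two-sided permutation p = 0.375). It was -0.0172 ± 0.108 in replicate 1 and -0.0301 ± 0.0589 in replicate 2 (SD, n = 8) and did not separate them. Adjusted over both ratios, the p of ACTB and GAPDH were 0.954 and 0.75.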

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

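The tests of the stress genes, of the response by day and replicate and of PAK4 were chosen only after those results were seen. The splits of the arrays within days were chosen before the data were examined. Those that part the pairs rest on a pairing that was taken up after the data were seen. The lists tested by splits, ERG-positive and neuroendocrine, were those with the smallest adjusted p on average.

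Mitotic genes had a more positive ERG shRNA effect on day 10 than on day 1 (median 0.61, 30 of 30 members positive, adjusted p = 0.00173, adjusted p = 0.86 with an estimated correlation, direction turned without ERG shRNA day 10 replicate 1), with list means of 0.95 and 0.33 in the replicate 1 and 2 pairs of day 10 and of -0.01 and 0.07 in those of day 1. S-phase genes differed between these days in the other direction (median -0.31, adjusted p = 0.027, adjusted p = 0.86 with an estimated correlation, direction turned without ERG shRNA day 10 replicate 2), with list means of -0.11 and -0.50 on day 10 and of -0.14 and 0.11 on day 1. Genes often higher in ERG-positive prostate cancer had a more negative effect on day 10 than on day 1 (median -0.19, adjusted p = 0.0219, adjusted p = 0.537 with an estimated correlation), with list means of -0.64 and -0.66 on day 10 and of -0.53 and -0.30 on day 1.

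The arrays were regrouped 2 against 2 within each day, which allows 648 splits, of which 100 were used, the real one among them. The real split called 978 genes on average, the median other 0, and 3 of the 100, itself included, called as many. The other 2 called 1249 and 1207 genes and set mainly replicate 2 against replicate 1 arrays, so they follow the structure of the samples. The real count with the pairs as blocks was 2588, but no other split was run in that fit, so it does not show that the real split exceeds these. Among splits that part all 8 pairs, as the real one does, 1 of 100 of the 128 possible called as many, itself, and the highest other, 532, had only the day 1 replicate 2 pair swapped. For the number of lists past the threshold, 8, 2 of 100 such splits did as well, with a highest other of 8 and a median of 4. For the ERG-positive list 1 of 100 had as small an adjusted p and the smallest other was 1.4e-09. For the neuroendocrine list it was 2 of 100, and 1 other split had a smaller adjusted p, 7.5e-13. Few of the splits drawn did as well as the real one, which makes a chance division of the arrays less likely but does not exclude it. The number of lists does not show which of the 8 hold, since other such splits called a median of 4.

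ATF4 stress genes differed between the replicates of days 3 and 7 in both arms, by at least 1.93 on the log2 scale of the list mean. RNA integrity could be a cause, since the ACTB ratio separated the replicates, but the GAPDH ratio did not. The ACTB ratio also separated them on day 1, at 0.53 and 0.49 in replicate 1 against 0.24 and 0.32 in replicate 2. The stress list on that day had 8.55 and 8.49 against 8.57 and 8.58 (control and ERG shRNA in each). Within replicate 1 the stress list was 2.071 higher on day 10 than on the other days, while the log2 ACTB ratio moved by -0.0341. These values argue against the integrity that the ACTB ratio measures as the cause. The GAPDH ratio moved by 0.188 in that last comparison, so integrity by GAPDH is not decided. A denser or more depleted culture in replicate 2 could lower the mitotic list as well, and that list differed by -0.304 between replicate 2 and replicate 1 on day 3, by -1.91 and -1.54 in the control and ERG shRNA arms on day 7, and by -1.10 and -1.72 on day 10, where the stress list differed by only -0.06 and 0.33, so these values do not decide. What differed between the replicates stays open, a technical difference and a different onset over the days in each replicate included.

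The response in the genes changed on average, aligned to their direction, had a median of 0.60 in the replicate 1 pair of day 1 and of 0.32 in the replicate 2 pair, over genes selected on these same arrays. In replicates 1 and 2 it was 0.70 and 0.50 on day 3, 0.79 and 0.68 on day 7 and 0.76 and 0.66 on day 10. A difference between the cell pools that stayed constant over the days would give an effect that does not grow. An exact one-sided permutation of the days within replicates gave p = 0.00694 for a rise with day over 576 permutations. The rise had been seen before its direction was tested. For the median of these genes, the permutation argues against a constant difference as the only source. It does not reach a pool difference that showed more on later days, and stress and mitotic levels changed over the days in both arms. Single genes, none of which passed the test between days, are not covered either. For the neuroendocrine list, with means of 0.64, 0.76, 0.71 and 0.85 on days 1, 3, 7 and 10, a fixed difference between the pools stays open. A smaller loss of ERG on day 1 in replicate 2 could give its smaller response, but the mean of the ERG probe sets differed by -0.085 in replicate 2 minus replicate 1, and its value of -0.92 lay -0.48 (SE 0.22 from the spread between pairs of a day) from the -0.44 that the smaller response would need, which counts against it but did not pass with 4 degrees of freedom. It stays open, as does a slower onset of later targets in replicate 2, and a second hairpin or earlier time points were not part of the series.

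PAK4 was lower in the control arm than in the ERG shRNA arm. If the control hairpin acted on PAK4, its fall from day 1 to day 10 might be larger in the control arm, and it was -1.02 there and -0.56 in the ERG shRNA arm, a difference of 0.453 (SE 0.3118, adjusted p = 1) that could not decide. An effect of the control hairpin and a rise after loss of ERG stay open, since no array lacked a hairpin or doxycycline. If the control hairpin did lower PAK4, that would be part of every difference between the arms reported here.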

How the results depend on the processing

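The fit with the pairs as blocks, with or without the estimated correlation, the fits without the day 7 or day 1 arrays and the gene families were chosen after seeing the data. For named genes, 2459 of 2666 values kept their side of the threshold, 175 lost the call and 32 gained it. None changed sign where the main fit or the alternative called the gene. Differences that were not called could change sign, as did those of MYC (-0.11 to 0.10), MKI67 (-0.47 to 0.0037) and CDK1 (-0.04 to 0.42). ERG kept its call throughout, with a log2 difference from -0.93 to -0.59. The count of genes changed on average, 978 in the main fit, ran from 653 to 2588 over all settings. Smaller changes of a count are not each listed below. On average over the days, the calls of the neuroendocrine and androgen-induced lists, the ERG-positive list outside the fit with both blocks and estimated correlation, and all 978 genes with the pairs as blocks were kept under the alternatives not named next. Where a left-out array leaves a group with 1 sample, that group is assumed to vary like the others. In simulated data without pairing, the day 10 test called 31% of genes at a log2 difference of 1 and the fit with blocks 0%, which does not measure the reach of the blocked fit in these paired arrays. Genes with a mean signal under 20.5 were not tested. Why a result changed under an alternative was not tested.

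With nothing added to the signal, the day 1 count was 1. With 60 added, the difference in effect between day 10 and day 1 and the test over all days each called 1 gene, and the mesenchymal list had an adjusted p of 0.0552. Without a filter, the counts of days 3 and 7 were 5 and 54, and the mesenchymal and interferon lists had 0.795 and 0.17. With the stricter filter, the day 1 count was 6 and the S-phase, interferon and hypoxia lists had 0.0776, 0.286 and 0.067. With the mean of the probe sets, the day 1 count was 7 and the mesenchymal list had 0.067. With every probe set as its own test, 1536 passed on average, 887 higher and 649 lower, and the luminal, basal, mesenchymal and Wnt lists had 0.00776, 1.33e-06, 0.223 and 0.00128. There each probe set counted as a separate list member, so genes with several weighed more, such as CD44 with 8 in the basal list. These list values therefore do not rest on more genes than the main fit. Without the variance trend, the counts of days 3 and 7 were 16 and 61, and day 10 minus day 1 of the effect called 1. Fits of only the arrays compared, with fewer samples, called 0, 6 and 1 genes on days 1, 3 and 7 and 274 on day 10. In the additive fit the mesenchymal list had 0.0577. With the estimated correlation the androgen, S-phase, mesenchymal, interferon, cholesterol and hypoxia lists had 0.467, 0.873, 0.426, 0.467, 0.498 and 0.471. Quantile normalization changed none of these results.

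With the replicate as a block, days 1, 3, 7 and 10 called 11, 77, 206 and 256 genes, day 10 minus day 1 of the effect 1 and of the control arm 569, and the mesenchymal list had 0.0502. In the fit with blocks for the pairs the average called 2588, days 1, 3, 7 and 10 called 109, 326, 799 and 888, day 10 minus day 1 of the effect called 5, and the mesenchymal and interferon lists had 0.0778 and 0.0612. The pairs changed no other call of the counts and of the lists on average, and of the named genes 12 gained a call and none lost one. Under blocks for the pairs together with the estimated correlation, the ERG-positive list had 0.127 and the androgen, S-phase, mesenchymal, interferon, cholesterol and hypoxia lists each had 0.527. Without the day 7 arrays the S-phase list had 0.059, and without the day 1 arrays the mesenchymal and interferon lists had 0.0976 and 0.0687.

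When each array was left out, counts ran from 0 to 22 on day 1, from 2 to 58 on day 3, from 11 to 146 on day 7 and from 3 to 163 on day 10. They ran from 0 to 1 for day 10 minus day 1 of the effect and from 0 to 16 for the control arm. The adjusted p of lists on average ran from 3.18e-05 to 0.639 for S-phase, from 0.0303 to 0.962 for mitotic, from 0.0208 to 0.135 for mesenchymal, from 0.0121 to 0.12 for interferon, from 0.0303 to 0.881 for ATF4 stress, from 3.31e-06 to 0.0567 for cholesterol, from 0.004 to 0.0916 for hypoxia and from 0.0489 to 0.261 for Wnt genes. For day 10 minus day 1 of the effect, directions reversed in 3 cases. The mitotic list (0.00173) had 9.75e-17 to 0.841, with 0.447 and a reversed direction without ERG shRNA day 10 replicate 1. The androgen list (0.769) had 0.00126 to 0.987, with 0.0122 and a reversed direction without ERG shRNA day 1 replicate 2. The S-phase list (0.027) had 1.71e-09 to 0.933, with 0.441 and a reversed direction without ERG shRNA day 10 replicate 2.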

Other observations

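Outside the fixed lists, 4 gene families and the genes that follow were chosen only after their values were seen, so the family p-values are not independent evidence. Of 8 measured synaptotagmins, many of them calcium sensors of vesicle release, SYT4 rose by 1.36 and SYT14 by 1.01 and 6 did not pass. The family had an adjusted p of 0.000407, 0.0153 with an estimated correlation and 7.95e-05 to 0.0889 over the alternatives, adjusted over the 4 families tested. SYT4 is also a member of the neuroendocrine list. Of 26 potassium channel genes, 5 rose, among them KCNMA1 by 1.70, KCNH6 by 1.28 and KCNK3 by 1.12, 2 fell, KCNS3 with -1.01 and KCNQ1 with -0.44, and 19 did not pass, with an adjusted p of 0.0693 for the family, 0.123 with an estimated correlation and 7.95e-05 to 0.621 over the alternatives. Of 21 collagen genes, COL5A2 (-1.38), COL12A1 (-1.27), COL2A1 (-1.19) and COL4A4 (-0.49) fell and 17 did not pass, with an adjusted p of 0.0646 for the family, 0.266 with an estimated correlation and 0.0178 to 0.358 over the alternatives. Of 4 ID genes, which encode inhibitors of basic helix-loop-helix factors, ID1 rose by 1.89 and ID3 by 1.54. ID2 (-0.35) and ID4 (-0.12) did not pass. The family had an adjusted p of 0.155, 0.342 with an estimated correlation and up to 0.575 over the alternatives.

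Among other genes past the threshold on average, the neurofilament NEFH rose by 2.10, the prostaglandin-degrading enzyme HPGD by 2.11, the secreted ligand WNT5A by 1.63, the B-cell transcription factor PAX5 by 1.52 and the neuronal adaptor BEX1 by 1.40. The progesterone receptor PGR fell by 1.59, the growth factor PDGFC by 1.59, the phosphatase DUSP4 by 1.37, the racemase AMACR, a marker of prostate cancer, by 1.33 and the hedgehog transcription factor GLI3 by 1.27.

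The share of higher genes among those changed on average was 57.9%, 58% after quantile normalization, 57.3% with nothing added to the signal and 50.7% with the pairs as blocks, and the median difference of all genes was -0.02.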
